A study of Homo sapiens with 20 samples.

How the data were processed

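The values were used as the submitters deposited them, in 1 table per experiment with 26485 gene rows each and 1 RefSeq isoform per gene symbol. HISAT2, bedtools, limma and the build hg38 are named per the submitters' processing notes, without versions, settings or the step each was used for, and strand handling in the counting is not stated there. The deposited unit is another one than the design assumed: the authors' values are reads per 1e+06 reads of the rows (RPM) divided by a quantity of the row, the stop coordinate minus a thousandth of the start coordinate. Multiplying each deposited value by that quantity gave columns that sum to 1e+06, and dividing by the smallest step gave whole reads in 100% of values at a tolerance of 0.001. The divisor is not the gene's length, so levels are given as RPM after it was removed, with no correction for the length of a gene. The isoform row of 1491 symbols differed between the tables and that of 24994 was the same.

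Because the tables hold this unit and not raw counts, limma 3.58.1 in R 4.3.3 was used, and DESeq2 and edgeR were not used. This was a choice, since whole reads were recovered and limma-voom was run on them as another setting. Library scaling was a trimmed mean of M values (TMM) written out for this purpose, with 30% of log ratios and 5% of abundances trimmed. A pseudocount of 0.5 was added to the scaled RPM before the log2. The 15958 genes with a mean of at least 0.5 RPM over the 20 libraries were tested by limma with a trend, with a term for condition and a term for experiment, and p-values were adjusted by Benjamini and Hochberg within each comparison. A call is an adjusted p under 0.05. Python 3.11.15 with matplotlib 3.10.9 drew the plots.

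Gene lists were fixed before the data were examined, as were the comparisons, the rule for named genes and most of the other settings. The p53 targets were 4 lists (feedback and cell cycle arrest, apoptosis, DNA repair and metabolism, other targets), also tested together. The other lists were cell cycle, immediate early, interferon, NF-kB, heat shock, unfolded protein and amino acid stress, cholesterol synthesis, NRF2, metallothionein and metal response, hypoxia, TGF-beta, Mediator and kinase module, ribosomal protein, nuclear long noncoding RNA, mitochondrially encoded and replication-dependent histone genes, markers of blood, of fibroblast and endothelium, of liver and neuron, and of epithelial identity. Lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, which asks whether a list's genes move on balance one way and does not compare them with other genes. List p-values were adjusted over the lists of a comparison, and that of all p53 targets together stands alone. A gene is said to have risen or fallen only where it passed limma's test over all genes or adjusted over the list alone, and a list where it passed camera at the preset correlation.

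The rule for named genes took, in each comparison, up to 10 called genes with the largest and 10 with the smallest fold change, a panel of 18 p53 genes, and up to 4 members of each list with a call, by p-value in the direction of the call. No gene was called, so the first part named none. Genes outside the rule are named as such. Some genes that the rule takes are not reported here.

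Same-numbered libraries of an experiment were taken as pairs, from the values alone, since no label states it. Deviations of same-numbered libraries from their condition means correlated across genes at 0.286 to 0.585 in experiment 1 (12 pairs) and 0.877 to 0.940 in experiment 2 (18 pairs). With 2 replicates the deviations mirror each other, so both replicate numbers of experiment 1 give the same values. The libraries themselves correlated at 0.965 to 0.996 with the same number and 0.953 to 0.997 with other numbers in experiment 1, which does not tell pairs apart. In experiment 2 they correlated at 0.990 to 0.996 and 0.931 to 0.946. A fit with the 5 replicate numbers as blocks therefore stands beside the one with the experiment term wherever it changes a call or moves a count by more than 1.5 times, and is named as the blocked fit.

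Other settings chosen before were other scaling factors, other filters, pseudocounts of 0.1 and 5, limma-voom, each experiment alone, no experiment term, 8 group means, the blocked fit, structural RNA rows left out, a fold of at least 1.5, and each library left out in turn. Added after the data were seen were the blocked fit with library weights, with limma-voom, with a correction for gene span and without the library that stood apart, each experiment alone with blocks, experiment 1 without that library, the metallothionein list without rows of near-equal reads and without MT1X too, and the other lists without that library. In a test of the procedure with changes put into 200 genes, the experiment term recovered 12% of genes changed 1.5-fold, 66% at 2-fold, 80% at 3-fold and 96% at 4-fold, with 0 false calls among 15950 genes. The blocked fit recovered 96% at 1.5-fold and 100% above, with 16 false calls. The simulated reads had the mean of each block, a dispersion of 0.01 for every gene, the same change in both experiments and no library that stood apart. That dispersion was set and not estimated from the real libraries, so these shares do not give the power in the real data.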

Results

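RNA from nuclei of HCT116 cells, a colorectal carcinoma line with wild-type p53, was sequenced after ribosomal RNA depletion with a directional kit. The cells were electroporated with water or with 10 µM (per the labels) of a stapled peptide meant to block the binding of p53 to Mediator, the coactivator complex that links transcription factors to RNA polymerase II. They then stood for 3 hours in 0.1% DMSO, without or with 10 µM Nutlin-3a, which frees p53 from its ubiquitin ligase MDM2, and 200 nM peptide was added to the medium of the peptide wells. Each of the 4 conditions had 2 replicates in experiment 1 and 3 in experiment 2, which made 20 libraries and 5 per condition. Gene rows held 36717795 to 63896604 reads per library in experiment 1 and 18787172 to 47407746 in experiment 2. Epithelial genes were abundant, with a mean over the 20 libraries of 239 RPM for the adhesion molecule EPCAM and 1385 RPM for the keratin KRT8, while the leukocyte gene PTPRC had 0.0265 RPM. Of the fibroblast collagens COL1A2 had 0.000937 RPM, COL3A1 0.0256 RPM and COL1A1 29.6 RPM.

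The experiments differed in composition. Ribosomal, 7SL and other structural RNA rows took 16.9 to 26.3% of reads in experiment 1 and 1.67 to 5.29% in experiment 2, and libraries of different experiments correlated at 0.768 to 0.875 across genes, which are not independent replicates. The 51 histone genes had a median level of 110 RPM in experiment 1 and 0.286 RPM in experiment 2. The structural row RN7SK took 0.239 to 0.460% of reads in experiment 1 and 0.000486 to 0.00235% in experiment 2. The libraries of the experiments thus did not hold the same kinds of RNA in like shares, and the cause was not tested. In experiment 1, replicate 2 of Nutlin with water stood apart. It correlated at 0.955 with replicate 1 of its group, against 0.992 to 0.997 between replicates of the other groups, and its 10 most abundant rows took 43.5% of reads.

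Nutlin-3a without peptide asks which genes follow p53 activation. The p53 target genes rose, with 8 of 116 measured targets below 0 and a median log2 change of 0.30 (0.55 in experiment 1, 0.20 in experiment 2). CDKN1A, which encodes the cyclin-dependent kinase inhibitor p21, rose 2.26-fold (log2 1.18 ± 0.29 SE, 5 libraries per group, adjusted p = 0.0145 adjusted over the list alone), by 1.94 in experiment 1 and 0.66 in experiment 2, and was higher in 5 of 5 pairs. The antiproliferative gene BTG2 rose 2.45-fold (1.29 ± 0.39, adjusted p = 0.0360), the death receptors TNFRSF10B 1.54-fold (0.62 ± 0.13, adjusted p = 0.0121) and FAS 1.78-fold (0.84 ± 0.23, adjusted p = 0.0220), and the damage recognition gene DDB2 1.75-fold (0.81 ± 0.21, adjusted p = 0.0161), each over the list alone and each higher in 5 of 5 pairs. CDKN1A went from 37.6 ± 0.898 RPM (SD, n = 2) to 149 ± 43.7 in experiment 1 and from 48.9 ± 11.1 (SD, n = 3) to 80.0 ± 26.9 in experiment 2. MDM2, the p53 ligase and itself a p53 target, had 148 ± 5.71 and 366 ± 146 RPM in experiment 1, 44.3 ± 24.8 and 89.8 ± 72.8 RPM in experiment 2, and a log2 change of 0.96 ± 0.53 that passed over the list alone in the blocked fit (adjusted p = 0.000577) and not with the experiment term (adjusted p = 0.226).

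On hg38, the CDKN1A row lies at chromosome 6, 36678710 to 36685800, and the MDM2 row at chromosome 12, 68808172 to 68839849, with a start of 68809017 in the table of experiment 2. BTG2 lies at chromosome 1, 203305536 to 203307438, and DDB2 at chromosome 11, 47214942 to 47238849. TNFRSF10B lies at chromosome 8, 23020136 to 23068894, with LOC286059 on the opposite strand, and FAS at chromosome 10, 88990531 to 89015785, with FAS-AS1 on the opposite strand. These are spans of the listed isoforms, introns included.

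Adjusted over the list alone, 13 p53 targets rose and 0 fell, and in the blocked fit 61 rose and 1 fell, the apoptosis inhibitor BCL2L1 (log2 -0.21, chosen after its values were seen). The 15 feedback and cell cycle arrest genes had a median of 0.49 and 13 of 15 above 0, and the phosphatase gene PPM1D rose in the blocked fit (0.49, adjusted p = 0.00278). All 18 apoptosis genes were above 0, with a median of 0.39, and PHLDA3, an AKT inhibitor, rose by 1.19 ± 0.28 and BBC3, which encodes the BH3 protein PUMA, by 0.92 ± 0.27. Of 21 repair and metabolism genes 20 were above 0 (median 0.42), and the excision repair gene XPC rose by 0.54 ± 0.13, the lesion bypass polymerase gene POLH by 0.69 and the AMPK subunit gene PRKAB1 by 0.57. Of 62 other targets 57 were above 0 (median 0.24), with rises of DRAM1 (0.64 ± 0.15), ZNF337 (0.48 ± 0.12) and IKBIP (0.54). The ferredoxin reductase gene FDXR had 1.31 in experiment 1 and 0.05 in experiment 2.

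The list of all p53 targets passed camera with an estimated correlation (p = 3.33e-06, and 0.000536 in the blocked fit) and fry (p = 0.000348, and 0.000179 blocked), and its 4 parts had adjusted p-values with an estimated correlation of 2.0e-05 to 0.000363, and 0.00604 each when blocked. For experiment 2 the p with an estimated correlation was 0.000679 from the group means and 0.0167 when these were blocked, and 0.0764 in a blocked fit of experiment 2 alone, which loses the call. Of the 116 targets 42.2% were higher in all 5 pairs, against 2.78% of the other genes and 3.125% for chance. Medians per pair were 0.48 and 0.54 in experiment 1 and 0.27, 0.28 and 0.06 in experiment 2, and a two-sided exact sign-flip test gave p = 0.0625, the smallest that 5 pairs allow. Over all genes limma called 0 of 15958 genes, with 94 at an unadjusted p under 0.05 (71 up, 23 down), and limma-voom called 0. The blocked fit called 0, with 1160 at an unadjusted p under 0.05 (559 up, 601 down) and a smallest adjusted p of 0.0599, for TNFRSF10B, and blocked limma-voom called 15, of which 11 are in the p53 lists. The 13 targets became 0 without replicate 1 of Nutlin with water in experiment 1, 4 without replicate 1 of DMSO with water in experiment 2, 8 without replicate 1 or 2 of DMSO with water or replicate 2 of Nutlin with water in experiment 1, and 29 without replicate 3 of Nutlin with water in experiment 2. Without the library that stood apart, experiment 1 alone keeps 1 library of Nutlin with water, and there CDKN1A had 1.67 and MDM2 1.69.

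**Figure D1:**
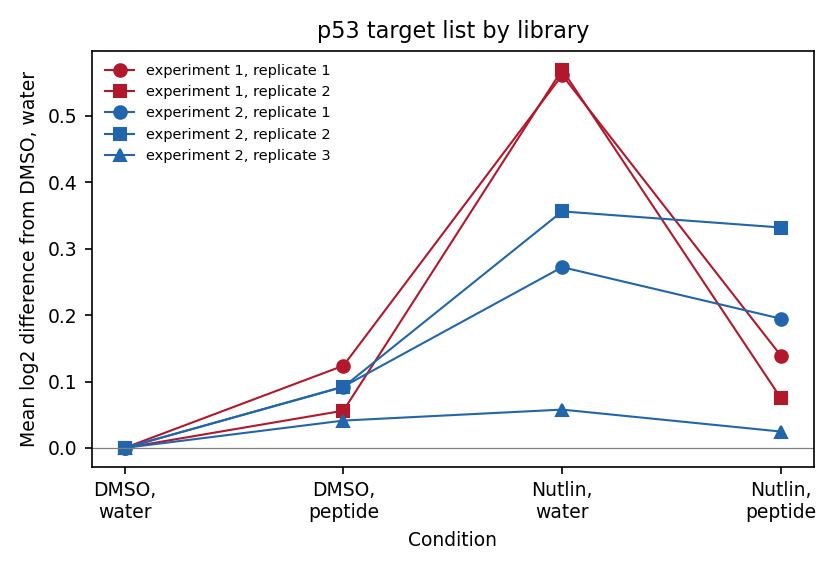
Mean log2 difference of the p53 target genes from DMSO with water of the same replicate number, 1 point per library, by condition and experiment. Nutlin with water lay at 0.56 and 0.57 in experiment 1, where Nutlin with peptide lay at 0.14 and 0.07, and Nutlin with peptide lay at 0.19, 0.33 and 0.02 in experiment 2 beside 0.27, 0.36 and 0.06 for Nutlin with water.

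Other lists moved with Nutlin-3a at the preset correlation and lost the call with an estimated one. The 24 unfolded protein and amino acid stress genes rose by a median of 0.18, with CHAC1, a glutathione-degrading enzyme, at 0.42, and had adjusted p = 0.190 with an estimated correlation. The 51 histone genes rose by 0.18 (adjusted p = 0.227 with an estimated correlation), with HIST2H4A at 0.34. The rows of HIST2H4A and HIST2H4B share their coordinates within each experiment, so the list holds these reads under both names, and the coordinates differ between the experiments. Medians of the 51 histone genes per pair were 0.09 and, with the library that stood apart, 0.92 in experiment 1. They were -0.07, -0.02 and -0.01 in experiment 2, where 41 of the 51 had a mean under 1 RPM. The 10 metallothionein and metal response genes rose by 0.23 (with an estimated correlation, camera p = 0.0130 unadjusted and 0.0596 adjusted). The 6 left without the rows of near-equal reads described with the peptide had 0.23 (unadjusted p = 0.00310 by the same test). The 5 left without MT1X too had 0.08 (unadjusted p = 0.0280). The shortened lists were not adjusted over the lists, so no call is given for them. SLC30A1, a zinc exporter, rose by 0.50 in the blocked fit (adjusted p = 0.000379 adjusted over the list alone) and was higher in 5 of 5 pairs. The 36 immediate early genes rose by 0.11, with the transcription factor BHLHE40 at 0.51, the 22 cholesterol synthesis genes by 0.09, and the 71 ribosomal protein genes fell by 0.08, with RPL7 at -0.23 (adjusted p = 0.983, 0.815 and 0.983 with an estimated correlation). The 45 cell cycle genes had a median of -0.11 and a call in the blocked fit only (adjusted p = 1.1e-06, and 0.310 with an estimated correlation). Without the library that stood apart, histone genes had 0.02 and immediate early genes -0.02, neither with a call, and unfolded protein genes had 0.11 and ribosomal protein genes -0.18. Without it NF-kB genes (-0.12) and epithelial identity genes (-0.18) fell, with adjusted p = 0.0312 and 0.708 with an estimated correlation.

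The peptide under Nutlin-3a asks whether blocking Mediator binding lowers the p53 response. The p53 targets fell, with 96 of 116 below 0 and a median log2 change of -0.18, by 0.44 in experiment 1, while experiment 2 had a median of -0.05. CDKN1A fell by 0.73 ± 0.29 (SE, 5 libraries per group) and was lower in 5 of 5 pairs, at -1.66 in experiment 1 and -0.11 in experiment 2, and passed over the list alone in the blocked fit (adjusted p = 0.0465). TNFRSF10B fell by 0.41 ± 0.13, FAS by 0.50 and BTG2 by 0.84 in the same fit (adjusted p = 0.0362, 0.0362 and 0.0402). In experiment 1, CDKN1A was at 149 ± 43.7 RPM (SD, n = 2) with Nutlin alone and 46.0 ± 4.60 with Nutlin and peptide, and in experiment 2 at 80.0 ± 26.9 (SD, n = 3) and 74.2 ± 25.6. MDM2 had -0.46 ± 0.53 (blocked adjusted p = 0.0656 over the list alone), with -1.11 in experiment 1 and -0.03 in experiment 2.

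Adjusted over the list alone, 0 p53 targets passed with the experiment term, with 0.376 as the smallest adjusted p of those named, and 17 fell in the blocked fit. The 18 apoptosis genes had a median of -0.33, and 10 of 18 fell in the blocked fit adjusted over that list alone, with TNFRSF10D, a decoy receptor, at -0.26. The 15 feedback and arrest genes had a median of -0.18, the 21 repair and metabolism genes -0.19 and the 62 other targets -0.17, with 3, 3 and 4 falls in the blocked fit, each adjusted over its own list alone. Among the 17 were NADSYN1 (-0.42), an NAD synthetase gene whose span holds MIR6754, PRKAB1 (-0.36), the autophagy gene DRAM1 (-0.44), the potassium chloride transporter gene SLC12A4 (-0.45), DGKA (-0.36) and ZNF337 (-0.28). BBC3 had -1.56 in experiment 1 and 0.02 in experiment 2, DDB2 -1.16 and 0.05, FDXR -1.21 and 0.08, and none of these passed in the blocked fit (adjusted p = 0.0659, 0.0635 and 0.107 over the list alone).

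For all targets the p with an estimated correlation was 0.000340, and 0.00870 blocked, and fry gave 0.0211 and 0.0120. With an estimated correlation the call was lost in a fit of experiment 2 alone (p = 0.204, and 0.452 blocked), in the blocked fit with library weights (0.0814, with a median of -0.12) and in the blocked fit without the library that stood apart (0.0556). The 4 parts had adjusted p = 0.00206 to 0.0148 with an estimated correlation, and 0.0898 to 0.124 when blocked. Without the library that stood apart this was 0.102 for the feedback and arrest genes and for the other targets, which lost that call. The medians were then -0.23 for the feedback and arrest genes, -0.19 for the apoptosis genes, -0.24 for the repair and metabolism genes and -0.10 for the other targets. From the group means, experiment 2 had p = 0.164 with an estimated correlation, and 0 targets passed in a blocked fit of those means, while 61 fell and 5 rose in experiment 1 in that fit, adjusted over the list alone. Of the targets 24.1% were lower in all 5 pairs, against 2.40% of other genes. Medians per pair were -0.37 and -0.51 in experiment 1 and -0.06, -0.04 and -0.04 in experiment 2, and the exact sign-flip p was 0.0625, the smallest possible. Over all genes limma called 0, with 80 at an unadjusted p under 0.05 (35 up, 45 down) and 0 by limma-voom, and the blocked fit called 0 with 1315 (771 up, 544 down). Blocked limma-voom called 3, named after their values were seen: RNU4-2 and GRAPL rose and ASTN2 fell, and 0 are p53 targets. RNU4-2 averaged 48.3 RPM with Nutlin and water and 126 with Nutlin and peptide in experiment 1, but 0.197 and 0.112 in experiment 2. ASTN2 averaged 103 and 56.4 RPM in experiment 1, but 1.09 and 0.981 in experiment 2. The calls of RNU4-2 and ASTN2 thus rest mainly on experiment 1. The 71 ribosomal protein genes rose by a median of 0.14, with 70 of 71 above 0 and RPL7 at 0.28, and had adjusted p = 0.852 with an estimated correlation. Without the library that stood apart they had 0.24, and heat shock (0.15), NRF2 (0.13), epithelial identity (0.17) and histone genes (0.08) rose, with adjusted p = 0.318, 0.102, 0.472 and 0.472 with an estimated correlation. Blocked calls also took in the cell cycle genes (0.10), immediate early genes (-0.05), heat shock genes and blood markers, with adjusted p = 0.574, 0.574, 0.574 and 0.565 with an estimated correlation. The median of the p53 targets was -0.30 without replicate 3 of Nutlin with water in experiment 2. Experiment 1 alone without the library that stood apart keeps 1 library of Nutlin with water. Its rises with Nutlin and its falls with peptide both rest on that library, so they are not independent.

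**Figure D2:**
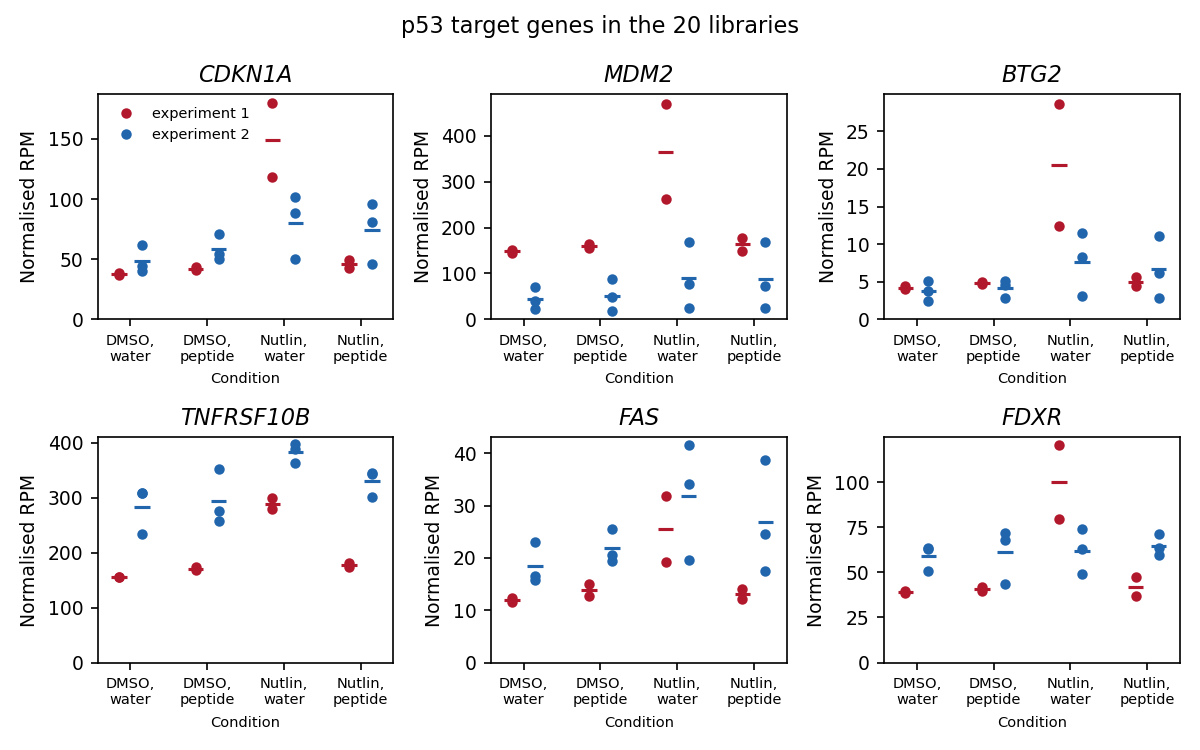
Scaled RPM of CDKN1A, MDM2, BTG2, TNFRSF10B, FAS and FDXR in each library, by condition and experiment. CDKN1A averaged 149 RPM with Nutlin and water and 46.0 with Nutlin and peptide in experiment 1, and 80.0 and 74.2 in experiment 2, and FDXR averaged 100.0 and 42.2 in experiment 1 and 61.9 and 64.6 in experiment 2.

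The peptide without Nutlin-3a asks what it does where p53 is not activated. The p53 targets rose slightly at the preset correlation, with 93 of 116 above 0 and a median of 0.08, 0.09 in experiment 1 and 0.07 in experiment 2. That call was lost with an estimated correlation (p = 0.0883, and 0.235 blocked). CDKN1A had 0.22 ± 0.29 (SE, 5 libraries per group) and was higher in 5 of 5 pairs, PHLDA3 had 0.33 and TP53INP1, a p53-induced stress protein gene, 0.28, and 0 targets passed over the list alone in either fit. The 10 metallothionein and metal response genes, which bind or move zinc, had a median of 0.57, but the highest values, 3.98 for MT1H and 3.11 for MT1F, come from rows that held near-equal reads in some libraries. The 6 genes left without these rows had a median of 0.18 (unadjusted camera p = 0.00586 with an estimated correlation, 0.00174 at the preset one). The full list had 0.000436 unadjusted with an estimated correlation. The shortened list was not adjusted over the lists, so no call is given for it. MT1X, the next row of that stretch, had 0.97. Without MT1X too, a choice made after its values were seen, the 5 genes left, MT1E at 0.20 among them, had 0.16. They did not pass even unadjusted (camera p = 0.227 with an estimated correlation, 0.216 at the preset one).

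Of the p53 targets 19.8% were higher in all 5 pairs, against 6.77% of other genes. They had a fry p of 0.296 and medians per pair of 0.11, 0.07, 0.10, 0.08 and 0.05, with an exact sign-flip p of 0.0625, the smallest possible. Their 4 parts had medians of 0.15, 0.08, 0.08 and 0.07 and adjusted p = 0.334 to 0.413 with an estimated correlation, and the apoptosis and repair parts had no preset call when blocked (adjusted p = 0.0515 and 0.0526). The full metallothionein list had adjusted p = 0.01002 with an estimated correlation and 0.0638 blocked. Heat shock genes rose by 0.13, with 16 of 16 above 0 and the chaperone genes DNAJA1 and HSPA1A at 0.14 and 0.18, Mediator genes by 0.07, with MED7 at 0.28 and MED19 at 0.19, ribosomal protein genes by 0.08 and histone genes by 0.10. The 4 blood markers fell by 0.16, with HBA1 at -0.41 from a mean of 0.843 RPM. With an estimated correlation these had adjusted p = 0.201, 0.334, 0.937, 0.334 and 0.334 in that order, and cell cycle genes (0.07) had a call in the blocked fit only, with 0.673. Over all genes limma called 0, with 14 at an unadjusted p under 0.05 (9 up, 5 down), limma-voom 0, the blocked fit 0 with 179, and blocked limma-voom 0. Without replicate 1 of DMSO with peptide in experiment 2 the p53 median was 0.07 and its preset call was lost.

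**Figure D3:**
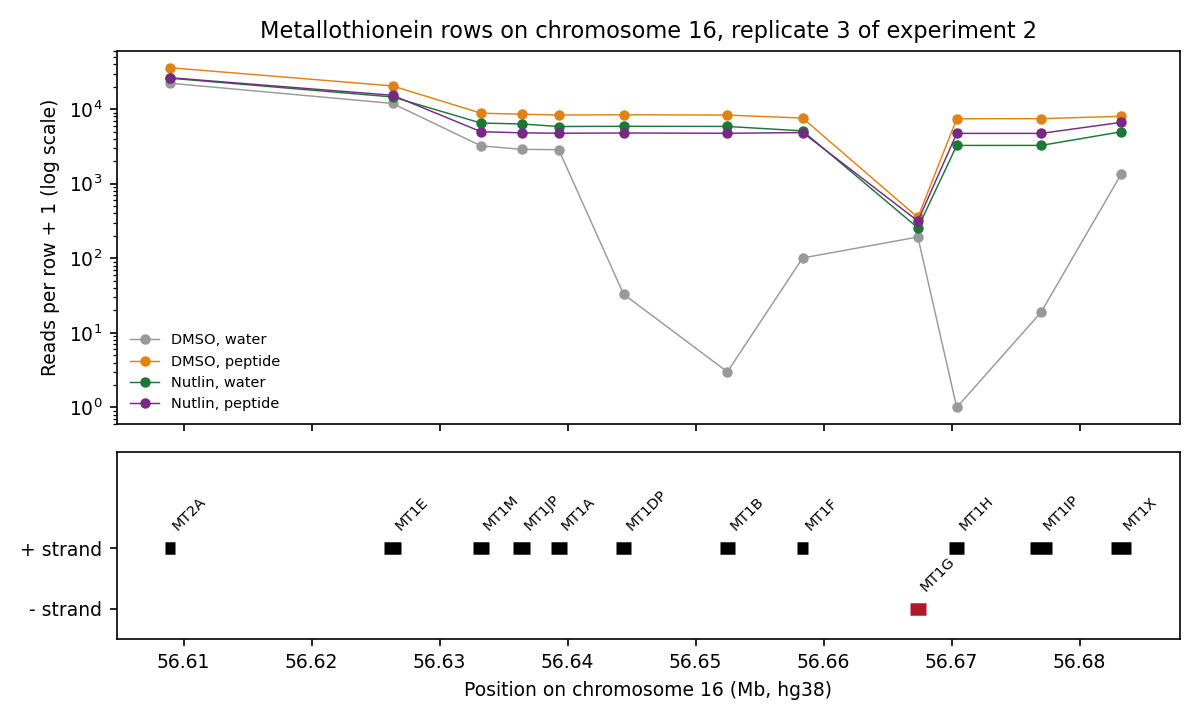
Reads plus 1, on a log axis, in each metallothionein row of chromosome 16 in replicate 3 of experiment 2, by condition. The MT1H row held 0 reads with DMSO and water and 7428 with DMSO and peptide, while MT2A held 22241 and 35908.

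Nutlin-3a in cells given peptide asks how much of the response is left. The p53 targets rose slightly at the preset correlation, with 79 of 116 above 0 and a median of 0.05, 0.04 in experiment 1 and 0.07 in experiment 2. CDKN1A had 0.22 ± 0.29 (SE, 5 libraries per group), MDM2 0.39 ± 0.53, with 0.02 in experiment 1 and 0.63 in experiment 2, and DDB2 -0.09 and 0.51. XPC at 0.19 and TNFRSF10A, a death receptor gene, at 0.18 were higher in 5 of 5 pairs, and 0 targets passed over the list alone. The 18 NRF2 targets of the oxidative stress response rose by a median of 0.08, with the heme oxygenase gene HMOX1 at 0.44, OSGIN1 at 0.26 and the glutathione synthesis genes GCLM at 0.21 and GCLC at 0.16.

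For all p53 targets the p with an estimated correlation was 0.0474, and 0.170 blocked, and fry gave 0.392. With 1 library left out that p ran from 0.0157 to 0.656 and passed in 6 of 20 cases, those without replicate 1 or 2 of Nutlin with peptide, replicate 1 of Nutlin with water or replicate 1 of DMSO with water in experiment 1, and replicate 3 of Nutlin with water or of Nutlin with peptide in experiment 2. Their 4 parts had medians of 0.12, 0.11, 0.06 and 0.03 and adjusted p = 0.148 to 0.737 with an estimated correlation. From the group means the p with an estimated correlation was 0.625 in experiment 1 and 0.0329 in experiment 2 (0.152 blocked), and 8 targets rose in experiment 2 in the blocked fit of group means, adjusted over the list alone. Of the targets 3.45% were higher in all 5 pairs, against 1.78% of other genes. Medians per pair were 0.03 and 0.01 in experiment 1 and 0.08, 0.19 and -0.05 in experiment 2 (exact sign-flip p = 0.3125). The NRF2 list had adjusted p = 0.0175 with an estimated correlation and 0.260 blocked. The unfolded protein genes rose by 0.08 (adjusted p = 0.847 with an estimated correlation), and cell cycle genes had -0.10, with a call in the blocked fit only and adjusted p = 0.526 with an estimated correlation. Over all genes limma called 0, with 26 at an unadjusted p under 0.05 (19 up, 7 down), limma-voom 0, the blocked fit 0 with 291, and blocked limma-voom 16. Of these 0 are p53 targets, and all are small noncoding RNA genes or pseudogenes, RNU4-2 among them. RNU4-2 averaged 34.2 RPM with DMSO and peptide and 126 with Nutlin and peptide in experiment 1, but 0.0771 and 0.112 in experiment 2. The p53 median was 0.00 and its preset call lost without replicate 2 of Nutlin with peptide in experiment 2, 0.11 without replicate 3, and 0.08 without replicate 2 of DMSO with peptide in experiment 2.

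The interaction asks whether the Nutlin-3a response was smaller with peptide than without. It was smaller for the p53 targets, with 106 of 116 below 0 and a median of -0.27, -0.50 in experiment 1 and -0.11 in experiment 2. CDKN1A had -0.95 ± 0.41 (SE, 5 libraries per group) and was below 0 in 5 of 5 pairs, at -1.82 in experiment 1 and -0.37 in experiment 2, BTG2 had -0.99 ± 0.55, FAS -0.72 ± 0.32 and TNFRSF10B -0.49 ± 0.18. Adjusted over the list alone, 0 targets passed in either fit, with blocked adjusted p = 0.0776 for FAS and TNFRSF10B, and 50 fell in experiment 1 in the blocked fit of group means.

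For all targets the p with an estimated correlation was 4.72e-05, and 0.00240 blocked, and fry gave 0.0197 and 0.0105. With an estimated correlation the call was lost in a fit of experiment 2 alone (p = 0.0667, and 0.277 blocked) and in the blocked fit with library weights (0.0634), where the median was -0.16. The 4 parts had medians of -0.34, -0.32, -0.25 and -0.23 and adjusted p = 0.000384 to 0.00260 with an estimated correlation, and 0.0246 each when blocked. Of the targets 22.4% were below 0 in all 5 pairs, against 1.80% of other genes, and medians per pair were -0.47 and -0.60 in experiment 1 and -0.19, -0.12 and -0.08 in experiment 2 (exact sign-flip p = 0.0625, the smallest possible). The metallothionein list was lower, by 0.32 (adjusted p = 0.0248 with an estimated correlation, 0.0464 blocked). The 6 genes left without the rows of near-equal reads had -0.21 (unadjusted camera p = 0.0144 with an estimated correlation, 0.00693 at the preset one). The full list had 0.00540 unadjusted with an estimated correlation. The shortened list was not adjusted over the lists, so no call is given for it. The 5 left without MT1X too had -0.17 and did not pass even unadjusted (p = 0.105 with an estimated correlation, 0.0903 at the preset one). Immediate early genes were lower by 0.10, unfolded protein genes by 0.10, cholesterol synthesis genes by 0.09 and histone genes by 0.18, and ribosomal protein genes higher by 0.06, with adjusted p = 0.991, 0.662, 0.991, 0.465 and 0.991 with an estimated correlation. Without the library that stood apart the first 4 had 0.02, -0.05, -0.07 and -0.02 and no call, ribosomal protein genes had 0.17 and the metallothionein list -0.50 (adjusted p = 0.221 with an estimated correlation). Over all genes limma called 0, with 28 at an unadjusted p under 0.05 (10 up, 18 down), limma-voom 0, the blocked fit 0 with 292, and blocked limma-voom 4. These were RNU4-2, RNU4-1, RNU5E-1 and GRAPL, named after their values were seen, with 0 p53 targets. Condition means of RNU4-2 were 34.2 to 126 RPM in experiment 1 but 0.0771 to 0.197 in experiment 2, so its call rests mainly on experiment 1.

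The share of the Nutlin-3a response left with peptide was read as the slope, over the 116 p53 targets, of the response with peptide on that without. With 0 called genes when all libraries were used, the planned slope over genes called in the other experiment could not be had. Over genes chosen in experiment 1 without the library that stood apart, the slope in experiment 2 was 0.637. That choice was made after the data were seen and rests on 1 library of Nutlin with water. The slope was 0.0231 in experiment 1 and 0.548 in experiment 2, with a mean of 0.286. Per pair the p53 targets gave 0.0127 and 0.0713 in experiment 1 and 0.361, 0.653 and 0.294 in experiment 2 (SD 0.191), and an exact permutation test between experiments gave p = 0.1, the smallest possible. In experiment 2 the slope was 0.212 without replicate 2 of Nutlin with peptide, 0.938 without its replicate 3, 0.285 without replicate 3 of Nutlin with water and 0.355 without replicate 1 of DMSO with water, and the mean over experiments was 0.481 without replicate 3 of Nutlin with peptide.

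The 2 experiments were compared directly, as experiment 2 minus experiment 1. For the p53 targets the Nutlin response without peptide differed by -0.37 (p = 0.00297 with an estimated correlation), the peptide effect under Nutlin by 0.44 (p = 0.000352) and the interaction by 0.41 (p = 0.00110), while the peptide effect without Nutlin differed by -0.02 and the Nutlin response with peptide by 0.08. Blocked and adjusted over the list alone, the peptide effect under Nutlin differed for CDKN1A (adjusted p = 0.000279), BBC3 (0.000270), FDXR (0.000171), DDB2 (0.000279) and MDM2 (0.00520). Over all genes limma called 0 differences for Nutlin without peptide and 0 for peptide with Nutlin, with 158 and 163 at an unadjusted p under 0.05, and 1, SNORD24, in each of the other 3 comparisons. The blocked fit called 3 and 52 in the former.

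Of 23 lists tested, 9 had no preset call in any of the 5 comparisons with the experiment term and all libraries. These were the cell cycle, interferon, NF-kB, hypoxia, TGF-beta and nuclear long noncoding RNA genes and the markers of fibroblast and endothelium, of liver and neuron, and of epithelial identity. Their medians lay between -0.12 and 0.13, the lowest preset adjusted p was 0.0542 and the lowest with an estimated correlation 0.607. In some of them median, mean and test differed in sign, as for the hypoxia genes with Nutlin alone (median -0.04, mean 0.01, test upward). The mitochondrially encoded list had 0 of 13 members among the rows. No direction of a list with a call turned under other scaling factors or without structural RNA rows, and the median of all genes stayed between -0.03 and 0.04.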

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

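The tests below were chosen after the result was seen, except the one that leaves out ribosomal and 7SL rows and the counts of other splits for the p53 medians.

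The response of the p53 targets differed between the experiments, by -0.37 for Nutlin without peptide (p = 0.00297), 0.44 for peptide with Nutlin (p = 0.000352) and 0.41 for the interaction (p = 0.00110), each a test of the difference itself by camera with an estimated correlation. Whether a smaller Nutlin response had the same share removed is not settled by the slopes. The lowest slope of a pair in experiment 2 was 0.294 and the highest in experiment 1 was 0.0713, so the slopes did not overlap. However, so few pairs cannot give an exact permutation p under 0.1. The slope of 0.294 is that of replicate 3, where the p53 median for Nutlin without peptide was 0.06, which leaves little response to take a share of. The library that stood apart is argued against as the only source of the difference for peptide with Nutlin, which was 0.39 without it. Experiment 1 then holds 1 library of Nutlin with water, so a trait of that library cannot be excluded. It cannot be told apart whether the peptide acted more strongly in experiment 1 or Nutlin-3a may not have acted in its libraries given both, where the p53 targets had a mean over pairs of 0.0204 for Nutlin with peptide, because no other sign of Nutlin-3a reaching those cells was measured. The libraries of the experiments also differed in composition. That difference is confounded with experiment, so its part in these differences cannot be told apart either.

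Replicate 2 of Nutlin with water in experiment 1 stood apart from the other libraries of that experiment. Its difference from replicate 1 correlated with log10 gene span at -0.42 across genes, against -0.203, -0.255 and -0.357 between replicates of the other 3 groups, and its median difference went from 0.46 among the 3990 shortest genes to -0.59 among the 3990 longest. Long genes thus held fewer reads relative to short ones in this library. RNA quality was not measured, so whether it was the cause cannot be told. The nuclear long noncoding RNA MALAT1 took 0.112% of reads in this library, against 0.269 to 0.393% in the others of experiment 1. The ribosomal row RNA45S5 took 14.4%, against at most 8.83% in the others. Whether the library held a smaller share of nuclear RNA was not tested. Ribosomal and 7SL rows taking the reads are argued against as the whole cause, since its highest correlation with another library of experiment 1 was 0.969 after these rows were left out, and 0.994 or more for each of the others. No biological explanation was tested, since its group holds 1 other library in that experiment.

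Plus-strand metallothionein rows on chromosome 16 held near-equal reads in some libraries. Of neighbouring pairs with at least 300 reads, 86.8% (59 of 68) lay within 5% of each other, against 3.38% of other same-strand neighbours (3001 of 88906). Induction of the metallothionein family is argued against by MT2A and the minus-strand MT1G. Over the 4 replicate numbers with both kinds of library, those with at least 300 reads of MT1H had 0.855 to 1.16 times the MT2A of the others. They had 0.110 to 1.41 times the MT1G. MT1H itself was at least 319.5-fold higher (against 3 reads per library), but a large fold follows from splitting the libraries by MT1H. Induction of these rows with MT1X, which had 1.96 to 4.20 times, stays open and was not tested. Gapped reads counted in every row they span are a possible explanation, which the share above cannot test, since the rows were picked for near-equal reads.

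The small nucleolar RNA row SNORD24 (chromosome 9, 133349396 to 133349470) differed between the experiments by 3.88 for peptide without Nutlin (adjusted p = 0.00185), by -4.71 for Nutlin with peptide (adjusted p = 0.000140) and by -4.33 for the interaction (adjusted p = 0.0365), with 81 and 63 reads, at most 1.96 RPM, in the DMSO with peptide libraries of experiment 1 and 24.9 to 48.4 RPM in the other libraries of that experiment.

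Other splits of the libraries within experiments were run for each comparison. The counts of genes test nothing here: limma called 0 in the real split, so 60 of 60 splits (100 of 100 drawn for the interaction) give as many by construction. The highest other count was 3, for Nutlin with peptide, and 0 for the rest. For the p53 median, 3 of 60 splits were as large as the real 0.30 for Nutlin without peptide (highest other 0.37), 8 of 60 as the real -0.18 for peptide with Nutlin (0.33 in size), 4 of 60 as 0.08 for peptide without Nutlin (0.10), 25 of 60 as 0.05 for Nutlin with peptide (0.15) and 11 of 100 drawn as -0.27 for the interaction (0.42), so chance was not excluded by these counts. Among the 16 splits that part all pairs, which cannot give a share under 0.05, the highest other medians were 0.27, 0.19, 0.06 and 0.07 in the same order, and the real one was the largest for Nutlin without peptide and for peptide without Nutlin.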

How the results depend on the processing

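The blocked fits with limma-voom, library weights, a gene-span correction or without the library that stood apart, and each experiment alone with blocks or without that library, were chosen after the data were seen, as were the metallothionein list without rows of near-equal reads, with or without MT1X, the other lists without the library that stood apart and all alternatives for the differences between experiments. The p53 median kept its direction for every comparison and alternative: 0.19 to 0.58 for Nutlin without peptide, -0.50 to -0.04 for peptide with Nutlin, 0.05 to 0.09 for peptide without Nutlin, 0.04 to 0.07 for Nutlin with peptide and -0.54 to -0.11 for the interaction. Leaving out each library gave 0.25 to 0.39, -0.30 to -0.15, 0.0564 to 0.101, 0.00207 to 0.105 and -0.38 to -0.23, and 0 called genes each time. With an estimated correlation, a fit of experiment 2 alone had p = 0.204 for peptide with Nutlin and 0.0667 for the interaction, and when blocked 0.452 and 0.277, and 0.0764 for Nutlin without peptide. Library weights gave 0.0814 for peptide with Nutlin and 0.0634 for the interaction, and the blocked fit without the library that stood apart 0.0556 for peptide with Nutlin. The preset p53 call was lost for Nutlin with peptide in experiment 1 alone (median 0.0483), also when blocked (median 0.0483) or without the library that stood apart (median 0.0584). It was also lost for peptide without Nutlin with library weights (median 0.0616), and the cause was not tested.

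Counts of 0 rose to 1 for Nutlin with peptide with no filter, to 1 each for peptide with Nutlin, peptide without Nutlin and Nutlin with peptide in experiment 1 alone, with or without blocks, to 2 for peptide with Nutlin in experiment 2 with blocks, and to 1 each for peptide without Nutlin, Nutlin with peptide and the interaction with 8 group means. For Nutlin without peptide they rose to 34 with library weights, 15 with blocked limma-voom, 5 in the blocked fit without the library that stood apart and 40 in experiment 1 without it. Blocked limma-voom gave 3 for peptide with Nutlin, 16 for Nutlin with peptide and 4 for the interaction, and experiment 1 without that library gave 58, 4, 2 and 19 for peptide with Nutlin, peptide without Nutlin, Nutlin with peptide and the interaction. Leaving that library out leaves 1 in its group, which is assumed to vary like the others. The cause was not tested. The blocked fit by itself called 0 genes over all genes in each comparison of conditions, as with the experiment term. Its changes to the calls of lists and of p53 targets stand with each comparison above.

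For the differences between experiments, leaving out structural RNA rows, SNORD24 among them, put the counts for peptide without Nutlin, Nutlin with peptide and the interaction at 0, and the p53 median for peptide without Nutlin at 0.0366, where it had been -0.02. Blocks gave 3, 52 and 6 for Nutlin without peptide, peptide with Nutlin and Nutlin with peptide, and without the library that stood apart 5, 25 and 510, and 2 for the interaction. Median-of-ratios factors gave a p53 median of 0.0711 for Nutlin with peptide, now called. The slope ranged with 1 library left out from -0.0172 to 0.0595 in experiment 1, 0.212 to 0.938 in experiment 2 and 0.117 to 0.481 for the mean, and the cause was not tested. DESeq2's test was not run on the recovered reads, a choice made because the tables do not hold raw counts, while limma-voom was run on them. Testing every row was the same fit, since no symbol repeats. The immediate early genes, called with all libraries, turned without the library that stood apart, to -0.0185 for Nutlin without peptide and 0.0189 for the interaction, and lost the call. As for depth, 3 reads were 0.160 RPM in the library with the fewest reads.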

Other observations

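The tests of the other p53-like genes and of the chromosome 14 rows were chosen after their values were seen, as were these genes.

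GRIN2C and ASTN2, both outside the p53 lists, followed the same course in experiment 1. GRIN2C, an NMDA receptor subunit gene (chromosome 17, 74842023 to 74859884), had 7.24 ± 0.387 RPM (SD, n = 2) with DMSO and water, 25.8 ± 4.94 with Nutlin and water and 3.97 ± 0.244 with Nutlin and peptide. In experiment 2 it had 5.37 ± 2.71 (SD, n = 3), 7.95 ± 5.14 and 8.72 ± 7.73, and its peptide effect under Nutlin differed between the experiments in the blocked fit (adjusted p = 0.00111). The GRIN2C row lies close to that of FDXR, a gene of the p53 lists (chromosome 17, 74862497 to 74868565). Whether GRIN2C changed independently of FDXR was not tested. ASTN2, a neuronal adhesion gene, had 55.2, 103 and 56.4 RPM in experiment 1 and 0.910, 1.09 and 0.981 in experiment 2. LINC01021, a long noncoding RNA, had 0.55 and 0.87 for Nutlin without peptide and was higher in 5 of 5 pairs, and had -0.66 and -0.20 for peptide with Nutlin and was lower in 5 of 5.

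The matricellular genes CYR61 and CTGF, targets of YAP and SRF, fell with peptide under Nutlin in experiment 2 when blocked, by 0.82 and 0.73, and were the 2 genes called there. In experiment 1 they had 0.02 and -0.07, and without Nutlin in experiment 2 -0.44 and -0.52. CYR61 ranged from 27.3 to 360 RPM over the 3 DMSO with water libraries of experiment 2.

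Rows of chromosome 14 around the 7SL genes changed between libraries of experiment 1. LRR1 held 1561 to 155015 reads. POLE2, a DNA polymerase subunit gene, held 26450 reads in replicate 1 of DMSO with peptide and 45126 in replicate 2 of Nutlin with peptide, and 726 to 2199 in the other libraries of that experiment. DNAAF2 held 44629 reads in replicate 2 of Nutlin with peptide and 528 to 1006 in the others. Neighbouring rows held near-equal reads, as the metallothionein rows did. RPL36AL held 45546 in replicate 2 of Nutlin with peptide, and KLHDC1 and KLHDC2 held 24750 and 25017 in replicate 1 of DMSO with peptide. The source of these reads was not tested, so they are not read as changes of these genes.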
